A study of Danio rerio with 4 samples.

How the data were processed

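RNA of whole zebrafish embryos (strain WIK) was measured on 4 two-colour Agilent arrays. Per the labels, each stage (3 and 6 days post fertilization, dpf) had an Msp mutant and a wild-type sample of RNA from 30 embryos raised at 28 °C, run in dye swap. On array 1 of each stage the mutant was labelled with Cy5, and on array 2 with Cy3. The labels do not state outright that both arrays of a stage held the same extracts. They name 1 sample of RNA per genotype and stage, so the dye-swapped arrays were taken as 1 replicate, and the design had 4 RNA pools. All arrays lay on 1 slide, so that slide could not be set apart.

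The scanner files came from Agilent Feature Extraction 10.5.1.1 with protocol GE2_105_Dec08, per the file headers, whereas the submitters' processing notes name version 8.5.1.1. Per the file headers, the probes were annotated to the zebrafish assembly danRer 6 (Zv 8). The deposited scanner files give each spot's median signal and local background as linear intensity in green (Cy3) and red (Cy5), the processed intensity after background subtraction and dye normalization, and LogRatio, which per the file headers is the log10 of red over green. The deposited series table was set against the scanner files, since its scale and direction are unstated. Its columns for array 2 of 3 dpf and array 1 of 6 dpf were deposited as log2 ratios of mutant over wild type of the same array, and its column for array 2 of 6 dpf was the mean log2 ratio of both 6 dpf arrays within 0.005. The deposited column for array 1 of 3 dpf was read as a score of unknown order, because it correlated with its own array at only 0.00288, and was not used. The median of each column was 0.

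Each array had 45220 spots, of which 1417 were controls. In 1 file 9 control spots with shifted cells were left out. The 43803 other spots held 43603 probes. Probes were named through the RefSeq accession (25173 probes), the symbol (3192) or an older symbol (1419) in the reference tables. Another 5558 probes kept the symbol of the file, and 8261 had none. No spot was saturated, and between 5 and 25 outlier spots per array were left out. Well above background were 59.6% to 69.2% of the probes in green and 73.5% to 74.8% in red. The number of arrays limits the precision.

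Values were computed in R 4.3.3 with limma 3.58.1, and files were read and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The background was corrected with normexp (offset 50) on the spot median signal, as the files lack the spot mean, and the local background median. Ratios were normalized by loess within each array with control spots at weight 0. The sign was turned so that each ratio is mutant over wild type, spots of a probe were averaged, and both arrays of a stage were averaged. A gene was represented by its brightest probe. Of 26621 genes with complete values, 18875 were kept because their probe was well above background on both arrays of at least 1 pool, and 9470 of those had more than 1 probe. For signals per pool, Aquantile normalization between arrays followed, and both dyes of a pool were averaged. Where a probe was not well above background on any array of a group, a fold is given as a lower bound against the lowest signal among probes well above background on the same arrays. These bounds rest on dye-balanced channel means.

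With 1 pool per genotype and stage no test was possible within a stage. Genes were counted by a size rule instead: an absolute mean log2 ratio of at least 1, the same sign with at least 0.5 on each array, and a signal well above background on both arrays in the genotype with the higher value. Genotype was tested with limma over the 2 stage values against 0, with 1 residual degree of freedom. For 6 against 3 dpf, limma was run on the 4 pools with genotype and stage as terms, and calls needed an absolute log2 change of at least 1. P-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The words rose, fell and changed are used for limma and camera calls, and higher and lower for values without a test.

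The 27 gene lists were MSP and HGF ligands, receptors and activating proteases; acute inflammation; acute phase proteins and complement; neutrophils; macrophages and microglia; lymphocytes and thymus; eosinophils and mast cells; enterocytes; intestinal goblet and enteroendocrine cells; exocrine pancreas; hepatocytes; erythroid cells; photoreceptors and phototransduction; lens; skeletal muscle; cartilage and bone matrix; DNA replication and cell division; p53 targets and apoptosis; heat shock and protein folding stress; circadian clock; cholesterol synthesis and lipid transport; yolk and vitellogenins; oxidative stress and xenobiotic response; interferon response; neurons; epidermis and keratins; and glucocorticoid response. Per stage, a list's median log2 ratio was set against 10000 random lists of equal size, matched on mean signal in 20 bins. The genes of random lists were drawn singly, without the correlation among members of a real list. A median beyond all random lists therefore describes the pools of that stage and is no test of genotype. Lists were tested with camera (preset correlation 0.01) on both limma fits, with an estimated correlation and fry as alternatives. The lists, the size rule, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Afterwards 2 members that had matched a list through the synonym of another gene were left out, by name alone.

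Named genes have a symbol rather than a clone or locus name, and were taken as follows: mst1, the 10 highest and 10 lowest genes past the size rule per stage, the 8 genes past it at both stages with the largest smaller value, the 5 limma calls over both stages with the smallest p in each direction, the 8 largest rises and falls between stages, and per list up to 4 members with the largest values. Further members of lists are named where few were called, and were then chosen after their values were seen.

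Alternatives were Agilent's processed signals, normexp with offset 10, no background subtraction, median centring in place of loess, the series table, no filter or a stricter filter on dim probes, the mean of all probes of a gene, leaving out each array, other variance priors and between-array normalizations, no minimum fold, and the dye-swapped arrays counted as samples. The procedure was tested on simulated data with known changes in 200 genes. Of 50 genes changed by a log2 of 1, 1.5, 2 and 3, the size rule at 3 dpf found 7, 40, 47 and 46. The measured sizes were smaller than the simulated ones, with a median of 0.78 for a log2 change of 1. Limma over both stages called all 50 genes at each size and 32 of 18673 unchanged genes. These 32 false calls stood beside 200 true ones, a larger share than the adjusted p threshold implies. For 6 against 3 dpf, 6, 39, 43 and 48 genes and 0 unchanged genes were called. Camera with the preset correlation called a list of 30 genes changed by 0.5 and 0 of the unchanged lists. With an estimated correlation, which uses 1 residual degree of freedom, the changed list was missed. The simulated pool noise was independent between genes, and its correlation in the real pools could not be measured. The real exocrine pancreas list had an estimated correlation of 1 over both stages. With 1 residual degree of freedom that figure only reflects members that moved the same way between the stages. The simulation therefore cannot show how often camera with the preset correlation falsely calls lists of correlated genes.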

Results

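Whole zebrafish embryos with a mutation in macrophage stimulating protein (Msp, gene mst1) were compared with wild type at 3 and 6 dpf. Msp is a secreted ligand related to hepatocyte growth factor, and its receptor is the tyrosine kinase Ron. Each stage had 1 pool of RNA from 30 embryos per genotype, hybridised on 2 dye-swapped arrays, so the 4 arrays gave 4 pools and no biological replicates within a stage. The median spot signal lay between 146.5 and 154 in green over a local background of 47.5 to 49, and between 167 and 187 in red over 87 to 87.5. Errors given as ± are the SD of the 2 arrays of a stage and measure labelling and hybridisation only. Log2 signals of the genotypes correlated across genes at 0.995 at 3 dpf and 0.994 at 6 dpf, and those of the stages at 0.932 in wild type and 0.943 in the mutant.

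The transcript of the mutated gene, mst1, was lower in the mutant on all 4 arrays. Its log2 ratio of mutant over wild type was -0.65 ± 0.06 at 3 dpf and -1.12 ± 0.16 at 6 dpf, and limma over both stages gave -0.89 (adjusted p = 0.0424). This call was lost without background subtraction (adjusted p = 0.077), and Agilent's processed signals gave larger differences of -1.75 and -1.97. The labels do not say where the mutation lies relative to the probe. The list of MSP and HGF ligands, receptors and activating proteases had 9 measured members with medians of 0.00 at 3 dpf and -0.05 at 6 dpf. On single arrays the medians were -0.03 and -0.20 at 3 dpf and -0.03 and -0.11 at 6 dpf. None of the 9 members was named as a gene of the receptor Ron, for which no value is given. The protease inhibitors spint1a and spint2 stood at -0.34 ± 0.09 and 0.29 ± 0.20 at 3 dpf. Camera did not call the list (adjusted p = 0.267), and mst1 was its only limma call, both over all genes and adjusted over the list alone.

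At 3 dpf the mutant pool had higher transcript of the protocadherin pcdh1g32 (log2 2.25 ± 0.23), of nabp1a, which encodes a single-stranded DNA binding protein (1.37 ± 0.04), and of the activity-induced transcription factors fosab (1.29 ± 0.05) and npas4a (1.23 ± 0.14). Transcript was lower for cox7a1, a subunit of cytochrome c oxidase (-2.12 ± 0.04), and for bach1b, a heme-regulated transcriptional repressor (-1.92 ± 0.01). It was also lower for rab42a (-1.54 ± 0.04), the ileal bile acid binding protein fabp6 (-1.52 ± 0.00), the MHC class I gene mhc1ze (-1.39 ± 0.12) and the biliverdin reductase blvrb (-1.36 ± 0.17). In total 61 of 18875 genes passed the size rule, 29 higher and 32 lower, and 36 of them had a symbol rather than a clone or locus name. Others among the highest with a symbol were stard8 (1.37 ± 0.19), mtif2 (1.26 ± 0.04), hspa12a (1.22 ± 0.21), dpy30 (1.12 ± 0.12), the Polycomb gene cbx7a (1.11 ± 0.03) and glb1l (1.1 ± 0.16). Among the lowest with a symbol were also nol12 (-1.33 ± 0.01), the annexin anxa6 (-1.24 ± 0.22), pla1a (-1.17 ± 0.01) and the globin ba1l (-1.16 ± 0.05). Of the other detected probes, 1 of 3 for stard8, 2 of 4 for fosab and 0 of 1 for mtif2 had the same sign. In the dimmer genotype mtif2 and ba1l were well above background on 1 of 2 arrays. The count has no test, and it was 271 with Agilent's processed signals, 107 with offset 10, 103 without array 2 and 29 with the mean of all probes of a gene.

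Among the gene lists at 3 dpf, cholesterol synthesis and lipid transport had the lowest median (-0.53), below all 10000 random lists, of which the lowest reached -0.12. Only 5 of its 29 measured members lay above 0. The fatty acid desaturase fads2 stood at -0.90 ± 0.03, and the sterol synthesis enzymes ebp, hmgcs1 and cyp51 at -0.86 ± 0.18, -0.77 ± 0.08 and -0.75 ± 0.05, though no member passed the size rule. The cholesterol exporter abca1a stood at 0.59 ± 0.07. Medians below all random lists were also found for skeletal muscle (-0.19 over 49 genes), enterocytes (-0.14 over 34), hepatocytes (-0.12 over 36), DNA replication and cell division (-0.12 over 39) and lens (-0.11 over 34). Medians above all random lists were found for acute inflammation (0.29 over 18 genes), interferon response (0.21 over 15) and photoreceptors (0.13 over 40). Random lists lack the correlation among the genes of a list, so these positions describe the pools and are no test. In the inflammation list the chemokine ccl34a.4 (well above background on 1 of 2 wild-type arrays) stood at 0.92 ± 0.10 and the itaconate-producing enzyme gene irg1l at 0.65 ± 0.15, whereas the iron hormone hamp stood at -0.76 ± 0.12. The neutrophil marker lyz stood at -0.69 ± 0.15, but the median of the 11 neutrophil genes was 0.01. Of the list members, igfbp1a of the hepatocytes (1.02 ± 0.21), fabp6 of the enterocytes and blvrb of the erythroid list passed the size rule. Agilent's processed signals gave a larger median of the same sign for cholesterol synthesis (-0.69).

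At 6 dpf the mutant pool had lower transcript of several digestive enzymes of the exocrine pancreas and several lens crystallins, and higher transcript of the red opsin opn1lw1 and the green opsin opn1mw2. The carboxyl ester lipase gene cel.2 stood at -1.43 ± 0.04, the carboxypeptidase cpb1 at -1.38 ± 0.02 and the crystallins crybgx and crygm2d13 at -1.49 ± 0.22 and -1.45 ± 0.30. The opsin opn1lw1 stood at 1.24 ± 0.07. Higher were also the ammonium transporter rhcgl1 (2.84 ± 0.09; not well above background in either genotype at 3 dpf), the gonadotropin-releasing hormone gnrh2 (1.87 ± 0.29), the pentraxin apcs (1.45 ± 0.36), and the interferon-related genes irf1b (1.53 ± 0.32) and ifi27.1 (1.36 ± 0.05). In total 98 genes passed the size rule, 48 higher and 50 lower, and 59 of them had a symbol. The highest with a symbol also held pcdh1g32 (1.91 ± 0.28), irg1l (1.33 ± 0.30), tcta (1.32 ± 0.17) and nabp1a (1.23 ± 0.05). The lowest with a symbol also held bach1b (-2.15 ± 0.16), rab42a (-2.06 ± 0.23), nol12 (-1.55 ± 0.13), tmem218 (-1.54 ± 0.00), the muscle gene klhl41b (-1.41 ± 0.09) and mhc1ze (-1.40 ± 0.15). The count has no test, and it was 322 with Agilent's processed signals and 163 with offset 10.

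The exocrine pancreas list had a median of -0.70 at 6 dpf over 22 measured genes, below all random lists, of which the lowest reached -0.15. In all 6 members were lower past the size rule, among them amy2a (amylase, -1.34 ± 0.04) and the elastase ela3l (-1.20 ± 0.05), and 1 member lay above 0. The lens list had a median of -0.52 over 34 genes with 4 lower past the size rule, including crygm2a (-1.23 ± 0.18) and cryba2b (-1.19 ± 0.04), and skeletal muscle had -0.12 over 49 genes. Both medians also lay below all random lists. Photoreceptors had a median of 0.40, and 38 of 40 members lay above 0. Of these, opn1lw1 and opn1mw2 (1.09 ± 0.31) passed the size rule, and the rod transducin gnat1 stood at 0.80 ± 0.02. Medians above all random lists were also found for interferon response (0.32), DNA replication and cell division (0.19), heat shock and protein folding stress (0.17) and macrophages and microglia (0.16). The macrophage gene mpeg1.2 stood at 0.80 ± 0.07 and the granulin gene grna.2 at 0.77 ± 0.08, and of the interferon list stat1b at 0.50 ± 0.08 and irf7 at 0.49 ± 0.00, but socs1a at -0.67 ± 0.05. Further list members higher past the size rule at 6 dpf were pomca (pro-opiomelanocortin, 1.16 ± 0.15), cyp7a1 (the rate-limiting enzyme of bile acid synthesis, 1.08 ± 0.20), col10a1a (collagen X, 1.04 ± 0.21) and ahrra (1.03 ± 0.13).

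**Figure D1:**
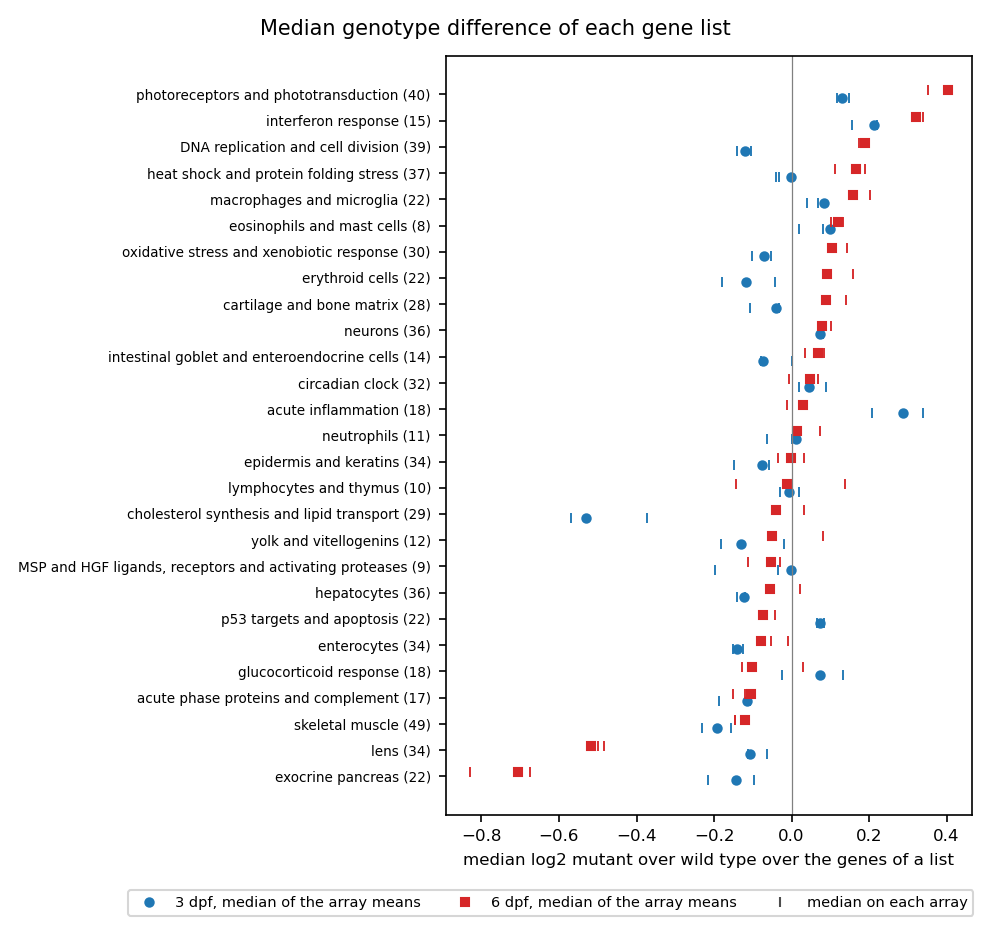
Median log2 ratio of mutant over wild type of each of the 27 gene lists, on the horizontal axis, with circles for 3 dpf, squares for 6 dpf and vertical ticks for the median on each single array; the number of measured genes stands in parentheses. Exocrine pancreas (-0.70) and lens (-0.52) lay lowest at 6 dpf, cholesterol synthesis and lipid transport lay lowest at 3 dpf (-0.53), and photoreceptors lay highest at 6 dpf (0.40).

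The stages shared 27 genes past the size rule in the same direction, 15 higher and 12 lower, and 0 in opposite directions. Independent lists would share 0.0737 higher and 0.0848 lower genes. Among genes with a symbol, the largest differences held at both stages were those of bach1b, pcdh1g32, rab42a, mhc1ze, nol12, nabp1a and hspa12a, followed by the keratin krt18b (-1.12 ± 0.11 at 3 dpf and -1.18 ± 0.14 at 6 dpf; its other detected probe had the opposite sign). Of the 61 genes at 3 dpf, 56 had the same sign at 6 dpf, and of the 98 genes at 6 dpf, 83 had the same sign at 3 dpf. Across genes, which are not independent replicates, the log2 ratios of the stages correlated at r = 0.469 (Spearman's rho = 0.335). Between single arrays of different stages this was 0.196 and 0.137 for opposite dye orientations and 0.446 and 0.548 for equal ones. The dye-swapped arrays of the same stage correlated at only 0.412 at 3 dpf and 0.403 at 6 dpf, below the equal orientations of different stages. Half-differences of the dye-swapped arrays, a measure of dye bias, correlated at 0.551 between the stages. Offset 10 gave 53 shared genes, Agilent's processed signals 117 and the mean of all probes 15.

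**Figure D2:**
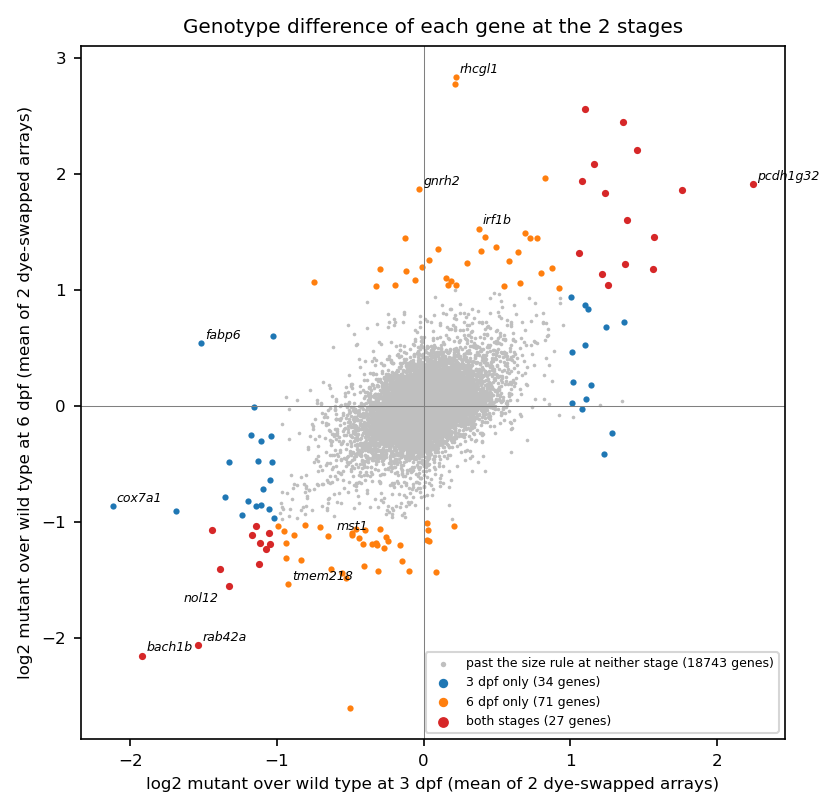
Log2 ratio of mutant over wild type of 18875 genes at 3 dpf (horizontal axis) and 6 dpf (vertical axis), each point a gene and the mean of 2 dye-swapped arrays, coloured by the stage at which the gene passed the size rule. The 27 genes past the rule at both stages lie in the lower left and upper right corners, and mst1 lies at -0.65 and -1.12.

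Limma over both stages, the only test of genotype with separate RNA pools, called 196 genes, 84 higher and 112 lower in the mutant. Among genes with a symbol, the smallest p of those that rose belonged to pcdh1g32 (log2 2.08, adjusted p = 0.00604), nabp1a (1.3, 0.00918), hspa12a (1.18, 0.00941), mtif2 (1.15, 0.0111) and tcta (1.19, 0.0111). Of those that fell it belonged to bach1b (-2.04, 0.00512), mhc1ze (-1.40, 0.00604), nol12 (-1.44, 0.00918), krt18b (-1.15, 0.00941) and the phospholipase pla1a (-1.14, 0.00941). Each of these kept its direction on all 4 arrays, which adds no support, since each passed the size rule at both stages and that rule requires it. The other detected probe of krt18b, and that of mtif2 at 3 dpf, had the opposite sign. Agilent's processed signals gave 30 calls (16 higher, 14 lower), among them 23 of the 196, and ended those of krt18b (adjusted p = 0.068), pla1a (0.0641) and tcta (0.085). The count rested on 1 residual degree of freedom, and it was 353 without array 1 of 3 dpf and 754 without array 2 of 3 dpf. In the simulation the share of false calls in this test lay above the adjusted p threshold. The share of false calls among the 196 may therefore also exceed it.

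Camera called 12 of the 27 lists over both stages, 5 up and 7 down. None of these calls held with an estimated correlation (adjusted p = 0.659 for each of the 12). That setting uses 1 residual degree of freedom, so hardly any list could pass. Skeletal muscle went from camera p = 9.69e-10 to 0.0851, though its estimated correlation was -0.02. The loss of the calls therefore speaks neither for nor against them. At the preset correlation the genes of a list count as nearly independent, so the p-values below do not measure the spread between pools. The estimated correlation was 1 for exocrine pancreas and 0.48 for both photoreceptors and lens, but -0.02 for skeletal muscle. With 2 stage values each gene's residual has only a sign. The figure therefore reflects how many members moved the same way from 3 to 6 dpf, and measures no correlation of pool noise. A value of 1 means that all measured members moved in the same direction. Exocrine pancreas genes fell (adjusted p = 7.44e-13), with a median of -0.14 at 3 dpf and -0.70 at 6 dpf; ctrl, prss1 and pdia2 were limma calls over all genes, and 11 members fell when adjusted over the list alone. Photoreceptor genes rose (7.44e-13), with pde6ga, prph2b and gngt1 called over all genes and 19 members called when adjusted over the list alone. Lens genes fell (9.79e-10) with 0 members called over all genes and 3 adjusted over the list alone. Skeletal muscle genes fell (6.54e-09), with myl1 and tnni2a.4 called over all genes and 10 members adjusted over the list alone. Cholesterol synthesis and lipid transport fell (1.45e-06), with fads2 (-0.85) and the sterol carrier stard4 called over all genes and 8 members adjusted over the list alone. Its median was -0.53 at 3 dpf but -0.04 at 6 dpf, where 14 of 29 members lay above 0 and the single arrays gave 0.03 and -0.03. The interferon response rose (0.000112) with 0 members called over all genes, and adjusted over the list alone 8 rose and 1 fell. Macrophages and microglia (0.00485) and neurons (0.00485) rose, enterocytes (0.00763) fell, and each had 0 members called over all genes and 0 adjusted over the list alone. Their medians at 3 and 6 dpf were 0.08 and 0.16, 0.07 and 0.08, and -0.14 and -0.08. The enterocyte median at 6 dpf was -0.05 on array 1 alone and -0.01 on array 2 alone. Hepatocytes fell (0.0128; medians -0.12 and -0.06) with 0 calls over all genes and 2 adjusted over the list alone, and their 6 dpf median was -0.05 on array 1 alone but 0.02 on array 2 alone. Acute phase proteins and complement fell (0.0345; medians -0.11 and -0.10) with cp, the copper carrier ceruloplasmin, called over all genes, and adjusted over the list alone 1 member rose and 2 fell. Acute inflammation rose (0.0413), with ptgs2b higher and hamp lower over all genes, and adjusted over the list alone 3 rose and 1 fell. Its median was 0.29 at 3 dpf but 0.03 at 6 dpf, where the single arrays gave 0.02 and -0.01. At 3 dpf the single arrays gave -0.22 and -0.10 for exocrine pancreas, 0.07 and 0.04 for macrophages, -0.06 and -0.11 for lens and -0.11 and -0.19 for the acute phase list. All 12 had an adjusted p = 0.659 with an estimated correlation. Members named here outside the rule for named genes (pdia2, prph2b, gngt1, stard4, ptgs2b) were chosen after their values were seen.

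The other 15 lists were not called for genotype, with adjusted p between 0.0652 and 0.994. Their medians at 3 and 6 dpf were 0.01 and 0.01 for neutrophils, -0.01 and -0.01 for lymphocytes and thymus, 0.10 and 0.12 for eosinophils and mast cells, and -0.07 and 0.07 for goblet and enteroendocrine cells. They were -0.12 and 0.09 for erythroid cells, -0.04 and 0.09 for cartilage and bone matrix, -0.12 and 0.19 for DNA replication and cell division, 0.07 and -0.07 for p53 targets and apoptosis, and 0.00 and 0.17 for heat shock. They were 0.05 and 0.05 for the circadian clock, -0.13 and -0.05 for yolk and vitellogenins, -0.07 and 0.10 for oxidative stress, -0.08 and 0.00 for epidermis and keratins, and 0.07 and -0.10 for the glucocorticoid response. On a single array the median turned its sign for lymphocytes and the glucocorticoid response at both stages, for neutrophils and goblet cells at 3 dpf, and for the circadian clock, yolk and epidermis at 6 dpf. Adjusted over the list alone, limma called 1 erythroid gene higher and 1 lower, 1 cartilage gene higher and 2 lower, 1 epidermis gene lower and 1 glucocorticoid gene higher. The erythroid genes were alas2, the first enzyme of heme synthesis, which rose, and blvrb, which fell; the cartilage gene cnmd (chondromodulin) fell over all genes too. Median, mean and camera direction differed in sign in 5 lists, all with an adjusted p of 0.994. Several lists overlap: other lists hold 6 hepatocyte, 6 glucocorticoid, 5 yolk, 2 acute inflammation, 2 macrophage and 2 circadian genes, and 1 gene each of the acute phase, neutrophil, eosinophil, enterocyte, exocrine pancreas, p53 and interferon lists.

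From 3 to 6 dpf, genes of the digestive pancreas rose most among genes with a symbol. The chymotrypsin-like ctrl rose by a log2 of 8.47 (adjusted p = 9.49e-07), the elastases ela3l, cela1.6 and ela2l by 8.41, 7.60 and 7.08, and the trypsins prss59.1 (above background on 1 of 2 mutant arrays at 3 dpf) and prss1 by 7.48 and 7.12. Chymotrypsinogen ctrb.1 rose by 7.21, and ctrb.2 was not well above background at 3 dpf, so that it rose by at least 149.8-fold (adjusted p = 7.22e-06). The largest falls among genes with a symbol were those of the calcium-binding casq2 (-3.11), fabp4b (-3.07), the cartilage link protein hapln1a (-3.05), the nuclear import factor kpna2 (-2.86), rcn3 (-2.83), calr3b (-2.81), the ribonucleotide reductase rrm2l (-2.80) and the actin acta1b (-2.79). Limma called 1945 genes with an absolute log2 change of at least 1, 934 up and 1011 down, and 1435 of them had a symbol. Without a minimum fold 11576 genes passed, and with Agilent's processed signals 4235. The test rested on 2 pools per stage and 1 residual degree of freedom.

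Between the stages camera called 13 lists, 9 up and 4 down, and none of them held with an estimated correlation (adjusted p = 0.681 for each of the 13). That setting again used 1 residual degree of freedom, so the loss of the calls decides nothing. As for genotype, the p-values at the preset correlation do not measure the spread between pools. DNA replication and cell division fell (median -1.85, adjusted p = 1.13e-15), with 32 of 39 members down, among them ccnb1 (-2.56), mcm5 (-2.51), mcm6 (-2.45) and rrm1 (-2.40). Cartilage and bone matrix fell (-1.26, 3.87e-07; 19 of 28 down, 1 up), with matn1 at -2.47 and col11a2 at -2.20. Erythroid cells fell (-0.61, 0.00031; 4 of 22 down), with the embryonic globins hbae3 at -2.53 and hbbe3 at -2.43. Heat shock and protein folding stress fell (-0.44, 0.00258, with 14 of 37 down and 3 up), among them the endoplasmic reticulum genes pdia6 (-2.31) and hspa5 (-2.21). Exocrine pancreas rose (4.76, 5.69e-10; 18 of 22 up), as did hepatocytes (1.79, 1.27e-10; 24 of 36 up, 1 down), with igfbp1b at 5.07 and the liver fatty acid binding protein fabp10a at 4.49. Enterocytes rose (0.86, 7.89e-07; 13 of 34 up, 1 down), with fabp6 at 6.01 and the peptide transporter slc15a1b at 3.68. The circadian clock rose (0.85, 1.47e-07; 12 of 32 up), with nr1d1 at 3.11 and per1b at 2.89, and the glucocorticoid response rose (1.05, 6.31e-07; 10 of 18 up), with klf9 at 2.73. Photoreceptors rose (0.60, 2.3e-05; 13 of 40 up, 3 down), with pde6ga at 3.71 and opn1lw1 at 3.70. Acute phase proteins and complement (0.81, 5.19e-05; 4 of 17 up), macrophages and microglia (0.25, 0.0112; 3 of 22 up) and the interferon response (0.29, 0.0142; 3 of 15 up) rose too. Each of the 13 calls had an adjusted p = 0.681 with an estimated correlation. The other 14 lists were not called (adjusted p between 0.0839 and 0.992). Among them 5 of 18 acute inflammation genes rose and 1 fell, with socs3a at 3.16, and 3 of 29 cholesterol genes rose and 8 fell. Lens had 3 genes up, with cryaa at 1.76, p53 targets 6 up and 1 down, oxidative stress 5 up and 1 down, skeletal muscle 1 up and 4 down, and epidermis 4 up and 6 down. Neurons had 1 up and 3 down, yolk 1 up, eosinophils and mast cells 1 up (cpa5 at 3.21), neutrophils 1 down and goblet cells 1 down (agr2 at -2.70), whereas MSP and HGF genes and lymphocytes had 0. Adjusted over the list alone, the counts were equal in every list. Median, mean and camera direction differed in sign in 7 lists, each with an adjusted p of at least 0.983.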

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

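The differences between stages in this part were not tested, since each stage held 1 pool per genotype, and no test was chosen after the values were seen. They are given because both 3 dpf arrays lay on one side of 0 and both 6 dpf arrays on the other. The same held for 1986 of all 18875 genes, while 4767 had all arrays on one side, so many such genes are found without regard to their function. Each value is the log2 ratio of mutant over wild type at 6 dpf minus that at 3 dpf.

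The ileal bile acid binding protein fabp6 was lower in the mutant at 3 dpf and higher at 6 dpf (difference 2.06). The activity-induced transcription factors npas4a and fosab were higher at 3 dpf and lower at 6 dpf (-1.65 and -1.52). The pentraxin apcs, the receptor repressor ahrra, the hormone precursor pomca and the embryonic globin hbae3 went from lower to higher (1.58, 1.36, 1.29 and 1.28). So did agr1 (1.22), the green opsin opn1mw2 (1.15), lect2l (1.09), the muscle troponin tnni2b.1 (0.95), the retinol binding protein rbp2b (0.95) and the sterol synthesis enzyme hmgcs1 (0.91). Apolipoprotein apoc1 (0.65), the collagen chaperone serpinh1b (0.62), the replication gene mcm5 (0.58), runx3 (0.49), adcyap1a (0.49) and the oxidase subunit cyba (0.28) went the same way. From higher to lower went the crystallin crygm2b (-1.10), gadd45ab (-0.88), bcl11ba (-0.73), rps27l (-0.67) and the keratin cyt1 (-0.66). Some of these genes lay near 0 at 1 stage, within the median SD of 2 arrays (0.10 at 3 dpf and 0.11 at 6 dpf). At 3 dpf these were crygm2b (0.03), cyt1 (0.01), opn1mw2 (-0.06), serpinh1b (-0.06) and cyba (-0.09), and at 6 dpf adcyap1a (0.08). For them the difference shows no reversal. For 2 further genes the computed difference is no measured size. The globin hbaa1 (0.78) was well above background in wild type at 3 dpf and on no array of the other pools, so that its 6 dpf ratio has no direction. The chemokine ccl34a.4 (-1.01) was not well above background in the mutant at 6 dpf, so that its ratio there is no measured fold.

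The medians of 6 lists lay on opposite sides of 0 at the stages on both arrays of each. DNA replication and cell division went from lower to higher (0.31), as did erythroid cells (0.21), oxidative stress and xenobiotic response (0.18), heat shock and protein folding stress (0.17) and cartilage and bone matrix (0.13). The heat shock median was -0.0002 at 3 dpf (-0.04 and -0.03 on single arrays), so its difference rests on 6 dpf. P53 targets and apoptosis went from higher to lower (-0.15).

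The arrays also carry spike-in control spots, which entered no comparison. Their median red signal was 3729, against 91 for negative control spots, and their median green signal was 1806 against 94.5. The mean log2 ratio of red over green of the 10 spike-in probes ran from -2.74 to 2.69, and the largest SD over the arrays of a probe was 0.17.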

How the results depend on the processing

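All alternatives here were planned, and none was chosen after the results were seen. No named gene past the size rule and no list median of at least 0.25 in size changed sign. Over all settings, 2541 named values and 452 list medians stayed within 1 SD of the arrays, and 559 and 196 moved further. Of the named changes between stages 1645 were kept, 16 became calls, 2 lost the call and 2 reversed: apoc1 was -0.34 with Agilent's processed signals against 0.68, and tcf7 ran from -0.0728 (without array 1 of 6 dpf) to 1.18 when an array was left out, against 0.55. Of the named limma calls over both stages 171 were kept and 8 lost. No setting moved the median of all genes by more than 0.1, but this was fixed in advance, since every setting centred each array.

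Agilent's processed signals gave 271 genes past the size rule at 3 dpf (61 as reported), 322 at 6 dpf (98) and 117 at both (27), which held 60 of the 61 and 95 of the 98. They gave 30 limma calls (16 higher, 14 lower) in place of 196 (84 higher, 112 lower), 4235 calls between stages in place of 1945, and -1.75 and -1.97 for mst1. Offset 10 gave 107, 163 and 53 genes (24 higher and 29 lower at both stages, against 15 and 12), and -0.99 and -1.49 for mst1. Without background subtraction mst1 was -0.52 and -0.93, and with median centring it was -0.72 at 3 dpf. The series table, with 3 dpf from array 2 alone, gave 383, 334 and 119 genes, 52 limma calls, a correlation of 0.400 between stages against 0.469, and -1.51 and -1.97 for mst1; it holds ratios only and could not be used for 6 against 3 dpf. No filter on dim probes gave 395 limma calls and a correlation of 0.419. The mean of all probes of a gene gave 29 genes at 3 dpf and 15 at both stages. With the arrays counted as samples, limma called 381 genes at 3 dpf and 579 at 6 dpf, where the spread measures labelling and hybridisation error only. It called 798 over both stages, where the spread also holds the difference between the stages. Without a minimum fold 11576 genes passed between stages. With camera at an estimated correlation, and with fry, 0 lists were called in either comparison, against 12 and 13. At an unadjusted p under 0.05 the former gave 0 and 0 lists, and fry 1 and 10. Camera with an estimated correlation could hardly call any list here, since it uses the 1 residual degree of freedom. A smaller offset enlarges the ratios of dim probes by construction, and more genes enter without a filter or a minimum fold; the cause was not tested for the other changes.

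Leaving out each array gave 61 to 103 genes at 3 dpf (103 without array 2), 207 to 754 limma calls (353 without array 1 of 3 dpf, 754 without array 2) and correlations of 0.343 to 0.428. No paired analysis was possible because the replicate numbers of a stage count dye orientations of the same pools. Signal over background limits dim genes, since 59.6% to 74.8% of the probes per channel were well above background.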

Other observations

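In the tests below, those of the sign of second probes, of a developmental delay, of dye bias and of the share of liver were chosen after the results were seen. The embryonic globins hbbe2 (0.94 ± 0.15), hbae3 (0.90 ± 0.14), hbae1.1 (0.73 ± 0.45) and hbbe1.1 (0.73 ± 0.16) were higher in the mutant at 6 dpf (log2, SD of 2 arrays). At 3 dpf their values were 0.08, -0.38, -0.24 and -0.20. The embryonic globin hbbe3 was not among them, at 0.02 ± 0.01 at 6 dpf (well above background on 1 of 2 wild-type arrays) and -0.22 at 3 dpf. Between stages hbae3, hbae1.1 and hbbe1.1 fell by 2.53, 2.29 and 1.71, and hbbe3 had a log2 change of -2.43. Of 39 cell division genes 2 lay above 0 at 3 dpf and 31 at 6 dpf.

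The following genes were called by limma over both stages and picked after their values were seen. Transferrin receptor 2 (tfr2) was lower in the mutant, at -1.06 and -1.10 at 3 and 6 dpf (adjusted p = 0.0111). Lower too were hamp, the hormone hepcidin that limits iron export (-0.83 over both stages, adjusted p = 0.0153), and ceruloplasmin cp (-0.58, adjusted p = 0.0337). Higher was alas2, the first enzyme of heme synthesis in red cells, at 0.52 and 0.63 (adjusted p = 0.0378). No list of iron or heme genes had been fixed, and none was tested.

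Genes that differed in the same direction at both stages, such as bach1b and pcdh1g32, may reflect variants linked to the mutated locus rather than loss of Msp. With 1 pool per genotype and stage, genetic differences between the pools elsewhere in the genome could not be told apart from loss of Msp. The test of linkage does not cover them. As the source of the calls as a whole, linkage was argued against, since 7.87% of the 127 limma calls with a known chromosome lay on that of mst1 in assembly GRCz12tu (exact 95% interval 3.84% to 14.0%), against 4.39% of all kept genes with a known chromosome, where at least 50% had been predicted. For the nearest neighbours it stays open: 3 of 120 (rbm19, rps26l and zc3h10) and 124 of 12459 other genes were called, a ratio of shares of 2.51 (one-sided Fisher exact p = 0.121), and the 95% interval of the odds ratio (0.512 to 7.81) holds 1 and values above 2, so the bound on p that had been set in advance could exclude nothing. Sequence differences under single probes were argued against as the source of the calls as a whole, since 78.7% of the second probes of 89 called genes had the sign of the first (exact 95% interval 68.7% to 86.6%). Without probe sequences, however, overlapping probes could not be recognised. The share among genes that were not called was not computed, so the 50% taken as the baseline is unchecked. Gene by gene they cannot be told apart from expression, as the second probes shifted by a median of 0.318 of the first (95% bootstrap interval 0.213 to 0.5), between the bounds set for either outcome, and 35 of 89 by at least 0.5 of it; an effect of Msp itself was not tested apart from these.

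The lower pancreatic enzyme transcripts of the mutant at 6 dpf could be part of a developmental delay. Dye bias as the source was argued against, because the list's median lay below 0 in both dye orientations (-0.83 and -0.68). A delay in proportion to each gene's change was examined in 1409 other stage-changed genes with a symbol, outside the pancreatic enzyme families. Their slope of the mutant effect on the change from 3 to 6 dpf was -0.0534 (95% bootstrap interval -0.0647 to -0.0416). For the list the ratio of its 2 medians was -0.148, which is an unlike measure. The interval resampled genes, not pools. The other genes had to pass the stage fit, whose residual holds the mutant effect's difference between stages, and the list's members did not have to. The comparison therefore cannot exclude a delay as the whole source. A delay as a part also remains a hypothesis, since the interval of the slope lies below 0. The other genes that rose by at least 3, by 2 to 3 and by 1 to 2 had median mutant effects of -0.16 (36 genes), -0.16 (89) and -0.10 (486). Of the 12 other lists that camera called between stages (all lost with an estimated correlation, adjusted p = 0.681), 8 had a median mutant effect at 6 dpf opposite in sign to their stage change, such as DNA replication and cell division (-1.85 between stages, 0.19 in the mutant), and 4 had the same sign, such as photoreceptors (0.60 and 0.40); an effect of Msp on the pancreas stays open and untested.

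For the lower cholesterol synthesis transcripts of the mutant at 3 dpf, background correction and normalization were argued against, as the median kept at least 93.8% of its size under the other corrections (between -0.50 and -0.69). In these pools the 29 cholesterol genes lay 0.41 below the 36 hepatocyte genes (difference -0.41, 95% bootstrap interval -0.54 to -0.13). Their shift was thus larger than that of the hepatocyte list. The interval resampled genes, not pools, and the lists were not matched on signal. The comparison therefore cannot exclude a smaller share of liver as the source of all or part of the shift. An effect of the loss of Msp stays open and untested.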
